A study of Tetrahymena thermophila CU428 with 6 samples.

How the data were processed

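Nucleosome positions were measured by MNase-seq in the macronucleus (MAC) and the micronucleus (MIC) of Tetrahymena thermophila strain CU428. Micrococcal nuclease cleaves the linker DNA between nucleosomes, and the protected fragments are sequenced from both ends, so that the midpoint of a fragment estimates a nucleosome centre. The 6 libraries formed 3 groups of 2, namely MAC after heavy digestion, MAC after light digestion and MIC after heavy digestion. Per the labels, 5 libraries were purified on a gel and 1, MAC light 1, on a sucrose gradient. The labels' protocols describe how MAC were isolated and carry no separate isolation for MIC. Nothing in the labels places the replicates in separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

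The fragment files the authors deposited list the start and end of each mapped fragment with no score, and the lengths in them ran from 117 to 261 bp, so longer and shorter fragments were removed before deposit. The 4 MAC libraries lay on macronuclear scaffolds and the 2 MIC libraries on micronuclear supercontigs, which share no coordinates. TopHat2 and featureCounts are named in the submitters' processing notes, with no version and no role; the genome builds and the treatment of duplicate and multiply mapped reads are not given in the sources used here. A deposited list held 252271 called nucleosomes of 147 bp on MAC scaffolds. A deposited table of counts held, for 60907 of these nucleosomes (24.1%), the raw counts of fragment centres of MIC heavy 2 near the nucleosome centre and in a wider window, made with featureCounts on fragments aligned to the macronuclear genome, per the file headers. How either list was chosen is not given in the sources used here. All 60907 were matched to called nucleosomes by identical coordinates. A share of 100% within 20 bp was therefore fixed in advance, and the 0.167% after random shifts of 60 to 140 bp is no test of it.

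The criterion behind the shorter list was examined on the values. At the listed nucleosomes the share of midpoints within 20 bp of the centre among those within 73 bp reached 60% in 98.0% of cases in MAC heavy 1, and the 1st percentile of this share was 59.3% in MAC heavy 1 against 12.5%, 30.4% and 27.3% in MAC heavy 2, MAC light 1 and MAC light 2. The 1st percentile of the midpoint count was 50 in MAC heavy 1 and 3 in MAC heavy 2. The list therefore tracked MAC heavy 1, whose values on it are selected. The windows of the deposited counts were taken as 20 and 73 bp. These sizes were inferred, and every value of MIC heavy 2 at listed nucleosomes rests on them. With 10 bp in place of 20 bp, the listed medians were 42.8% and 42.6% in MAC heavy and 37.9% and 35.5% in MAC light. The lower degree reported for MIC heavy 2, with a median of 45.4%, therefore depends on these sizes.

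The share of midpoints within 20 bp among those within 73 bp is called the positioning degree; midpoints spread evenly give 27.9%. For each library the median degree over called nucleosomes with at least 20 midpoints was computed after thinning to the smallest library. Distances between midpoints up to 1000 bp were tallied in equally thinned libraries and smoothed over 31 bp. The nucleosome repeat length was the slope of up to 4 peak positions, and the array amplitude was the height of the first peak above its neighbouring troughs, as a percentage of the mean from 100 to 900 bp. Fragments were also counted in 1 kb windows, and the coefficient of variation (CV) over windows on scaffolds of at least 100 kb measured unevenness. Because the MIC fragments could not be placed on the called list, nucleosomes were also called anew in each library, thinned to 152 fragments per kb, and their degree was measured in the other replicate of the group, at calls with at least 10 midpoints in both; this measure and the CV were chosen after seeing the data.

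Group differences of library values were tested with exact two-sided permutation tests, which with 2 libraries against 2 cannot give a p below 0.333. Counts in windows and at nucleosomes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, robust, Benjamini-Hochberg threshold 0.05). For windows, TMM scaling and filterByExpr were used. For positioning, midpoints within 20 bp were tested with the log of those within 73 bp as offset, at nucleosomes with at least 20 midpoints in every library; counts inside a window vary less than the model assumes, which the quasi-likelihood scale absorbs in part. Only MIC heavy 2 has counts at called nucleosomes, so in that test the lone MIC library was assumed to vary like MAC heavy. DESeq2 1.42.0 was an alternative for windows. Other computations used Python 3.11 with numpy and scipy. On simulated window counts with 200 changed windows among 101991, 2.99% of 1.5-fold, 59.7% of 2-fold and 100% of 4-fold changes were recovered with 7 false calls. A first simulation of positioning, with 1.25-fold and 1.5-fold changes both ways, recovered 0%, and it was replaced by losses of 1.25, 1.5 and 4-fold. With 200 of 178482 nucleosomes changed, 0%, 0% and 6.06% of these were recovered for MAC light versus MAC heavy, and with 17812 or 17813 changed by each fold 2.91%, 16.5% and 94.9%, with 359 false calls. For MIC versus MAC heavy, 0%, 2.99% and 87.9% were recovered with 200 of 54523 changed, and 15.7%, 46.1% and 99.3% with 8884 or 8885 changed by each fold, with 474 false calls. In these simulated counts the spread between libraries was assumed, not estimated from the data. Positioning losses were placed only at nucleosomes with a high degree over the pooled libraries. Simulated arrays of 190 and 200 bp were recovered as 190.0 and 200.0 bp. A simulated library with evenly spread midpoints and no arrays also returned a repeat length, of 109.7 bp. Faint arrays on a declining histogram, as in the MIC, were not simulated, so the accuracy of the MIC repeat length was not tested.

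Before the data were examined, the tests, the alternatives and a rule for naming genes were fixed. Tests of genes, gene starts, gene lists, ribosomal DNA and GC content were not run, because no genome or annotation in the coordinates of the files was used here. Windows of 1 kb replaced genes for MAC light versus MAC heavy, and the gene rule was applied to them without its annotation terms: among windows past the threshold, with libraries not overlapping between groups and a mean above the median, the 8 largest changes each way. Nucleosomes named from the shorter list were chosen after their values were seen. Alternatives included fragments of 140 to 160 bp, identical fragments counted once, no thinning, other windows and minimum counts, other scalings, a replicate block and leaving out each library. Coordinates are 1-based. Intervals of shares are exact Clopper-Pearson at 95% and cover counting error only, since PCR copies are not independent molecules.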

Results

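Tetrahymena thermophila is a ciliate that carries a transcribed, polyploid macronucleus and a largely silent germline micronucleus in the same cell. Fragment files of 6 MNase-seq libraries were analysed. MAC heavy held 41421572 and 25663549 fragments in replicates 1 and 2, MAC light 18877450 and 15556729, and MIC heavy 56036686 and 48120254. Fragments covered 102 Mb of MAC scaffolds and 158 Mb of MIC supercontigs, which gave 152 to 404 fragments per kb. Repeated fragments made up 5.78% and 5.30% of MAC heavy, 1.21% and 0.680% of MAC light, and 4.72% and 3.57% of MIC heavy.

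Fragment length separated replicates more than nuclei. The median was 188 bp in MAC heavy 1 and 159 bp in MAC heavy 2, 190 bp in both MAC light libraries, and 190 and 155 bp in MIC heavy 1 and 2. MIC heavy averaged 172.5 ± 24.7 bp (SD, n = 2) and MAC heavy 173.5 ± 20.5 bp (SD, n = 2), a difference far inside the spread between replicates (exact permutation test, p = 1.00). Its sign rested on single libraries, since the difference was 16.5 bp without MIC heavy 2 and 13.5 bp without MAC heavy 1. Fragments shorter than a called nucleosome made up 22.3% of MAC heavy 2 and 29.0% of MIC heavy 2 but 3.28% of MAC heavy 1 and 3.10% of MIC heavy 1. In both nuclei the library labelled heavy replicate 1 thus had a median length close to MAC light. The upper quartile was 205 bp in MAC heavy 1 and 210 bp in MIC heavy 1, against 215 and 217 bp in MAC light. Longer fragments were removed before deposit, so close medians do not show equal digestion.

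**Figure D1:**
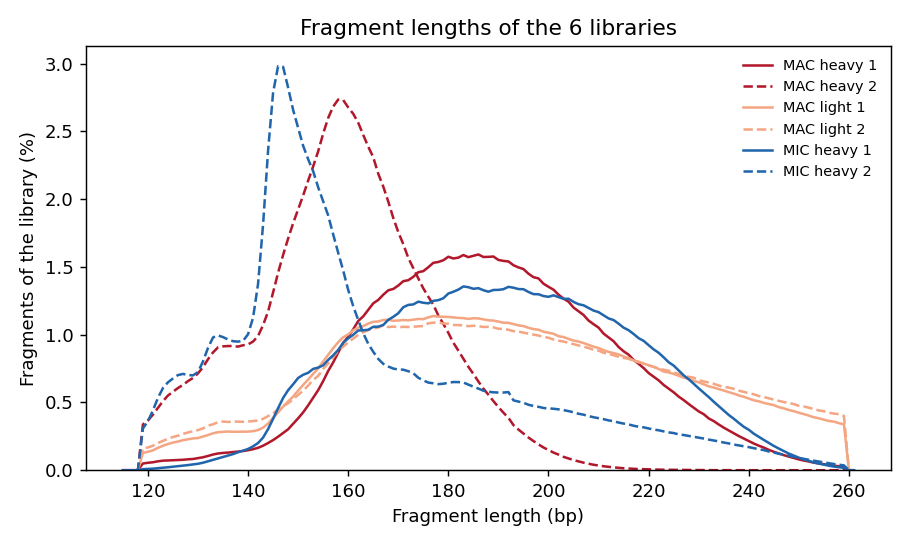
Percentage of each library's fragments (vertical axis) at each fragment length in bp (horizontal axis), 1 line per library, solid for replicate 1 and dashed for replicate 2. Replicate 2 of MAC heavy and of MIC heavy peaks at 158 and 146 bp, while the other 4 libraries spread around medians of 188 to 190 bp.

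The study set the nucleosome landscape of the MIC beside that of the MAC. Regular nucleosome arrays were prominent in the MAC and faint in the MIC. The array amplitude was 81.3% and 62.1% in MAC heavy, 54.6% and 49.2% in MAC light, and 8.15% and 8.94% in MIC heavy. The group means were 71.7 ± 13.6% for MAC heavy and 8.55 ± 0.557% for MIC heavy (SD, n = 2 each). Both MIC libraries lay below all 4 MAC libraries, with the smallest p the design allows for MIC heavy against MAC heavy (exact permutation test, p = 0.333). Among fragments of 140 to 160 bp the MIC amplitude rose to 29.2% and 17.3%, still below the lowest MAC value of 45.1%.

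The spacing of nucleosomes was close to 200 bp in the MAC. The repeat length was 199.1 and 197.7 bp in MAC heavy and 201.1 and 201.7 bp in MAC light. In MIC heavy it was 189.5 bp from 3 peaks and 185.0 bp from 2 peaks. The mean difference of MIC from MAC heavy, -11.2 bp, exceeded the spread between replicates (exact permutation test, p = 0.333, the smallest possible). After dividing out the slope of the histogram it was -6.10 bp, and on scaffolds of at least 500 kb -7.80 bp, both without overlap. Among 140 to 160 bp fragments it was -2.45 bp, with overlapping libraries. Positions of neighbours around called centres were read in steps of 10 bp. They lay at 210, 400 and 600 bp in MIC heavy 1 and at 210, 400 and 590 bp in MIC heavy 2. In both MAC heavy libraries they lay at 200, 400 and 600 bp. The repeat length is a slope over peaks, so the distance of any neighbour alone from the centre does not test it. The listed neighbours ran from 210 to 600 bp and from 210 to 590 bp in MIC heavy, against 200 to 600 bp in MAC heavy. The span was thus shorter in both MIC libraries, but a grid of 10 bp is too coarse to decide the size of the difference.

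**Figure D2:**
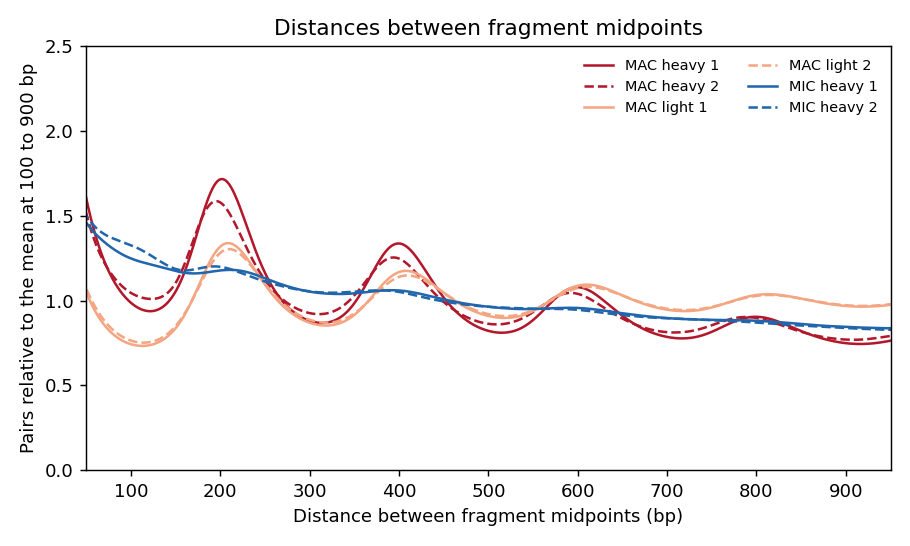
Number of midpoint pairs relative to the mean at 100 to 900 bp (vertical axis) against the distance between midpoints in bp (horizontal axis), smoothed over 31 bp, for the 6 libraries thinned to 1 size. The MAC libraries show 4 peaks about 200 bp apart, and the MIC libraries a declining line with shallow peaks.

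Single nucleosomes were also less sharply placed in the MIC. When nucleosomes were called in each library and measured in its replicate, the median positioning degree was 49.5% and 46.2% in MAC heavy, 43.3% and 43.8% in MAC light, and 36.7% and 37.1% in MIC heavy, where even spread gives 27.9%. MIC heavy averaged 36.9 ± 0.337% and MAC heavy 47.8 ± 2.34% (SD, n = 2 each), a difference of -10.9 points without overlap (exact permutation test, p = 0.333). The upper quartile of this degree was 65.5% and 59.6% in MAC heavy. It was 54.3% and 55.6% in MAC light, and 45.8% and 46.3% in MIC heavy. Around called centres the first neighbouring peak stood 3.31 and 3.38 times above the trough before it in MAC heavy, 2.95 and 3.06 times in MAC light, and 1.33 and 1.36 times in MIC heavy. The MIC supercontigs include DNA that the MAC lacks, so these values do not compare the same loci. The CV of fragments per 1 kb window was 76.0 ± 0.270% in MIC heavy and 91.6 ± 0.830% in MAC heavy (SD, n = 2 each), without overlap (exact permutation test, p = 0.333). Among 140 to 160 bp fragments the libraries overlapped, at 86.5% and 76.6% in MIC heavy and 110.6% and 85.7% in MAC heavy.

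**Figure D3:**
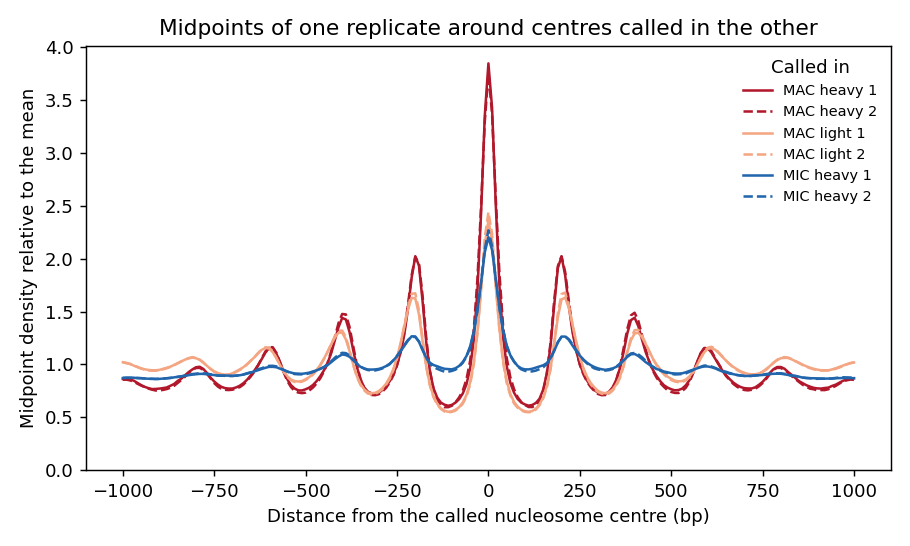
Midpoint density relative to its mean (vertical axis) against the distance in bp from nucleosome centres (horizontal axis), with centres called in the named library and midpoints from the other replicate. Density at the centre is 3.85 and 3.75 in MAC heavy, 2.36 and 2.44 in MAC light and 2.20 and 2.27 in MIC heavy, and neighbouring peaks are lowest in MIC heavy.

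The same loci could be compared through the authors' deposited counts of MIC heavy 2 at listed nucleosomes on MAC scaffolds. This holds only if their windows were 20 and 73 bp, as inferred. At the 47854 listed nucleosomes with at least 20 midpoints in all 5 libraries, the median degree was 45.4% in MIC heavy 2, against 70.0% and 72.1% in MAC heavy and 64.7% and 61.5% in MAC light. A degree of at least 60% counted as well positioned. After thinning every nucleosome to 20 midpoints, 20.5% (95% interval 20.2 to 20.9%) were well positioned in MIC heavy 2. In MAC heavy 2 the share was 77.5% (77.2 to 77.9%). These shares describe the thinned counts, and their intervals do not apply to the shares at full depth. At full depth the upper quartile of the degree in MIC heavy 2 was 52.3%. The lower quartile in MAC heavy 2 was 60.6%. The degree was lower in MIC heavy 2 than in MAC heavy 2 at 95.1% of these nucleosomes and lower than in MAC light 2 at 83.9%. In a test of single nucleosomes, 33601 of 54523 (61.6%) were less concentrated in MIC heavy 2 than in MAC heavy and 0 more concentrated (edgeR), with a median log2 ratio of -0.64. This count describes 1 MIC library, whose spread was taken from MAC heavy. The list tracked a high degree in MAC heavy 1, so a lower degree in the MIC is in part built into it. On the 47854 nucleosomes measured in all 5 libraries, with MAC light in the fit, 31540 were lower and 0 higher against MAC heavy. Without MAC heavy 1, which left 1 library against 1 and took the spread from MAC light, 22786 were lower and 29 higher, and against MAC light 11674 were lower and 82 higher.

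**Figure D4:**
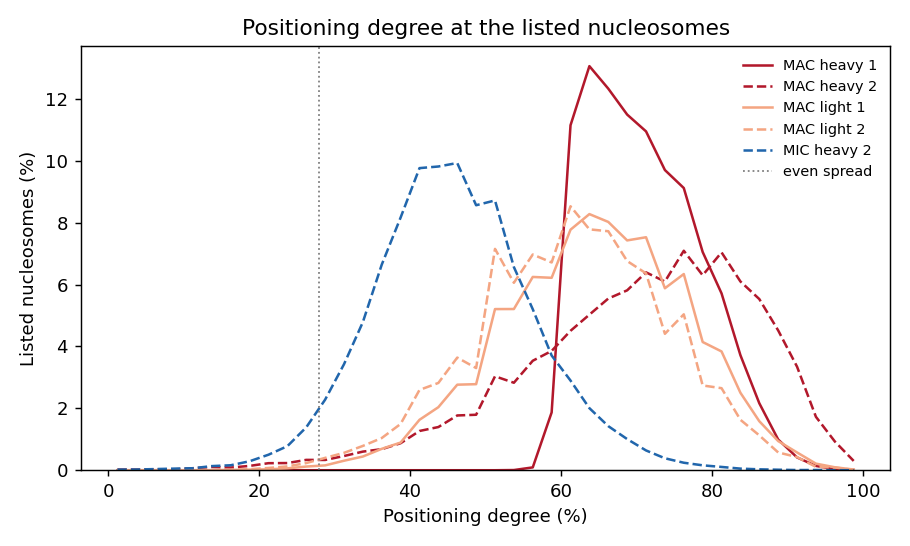
Percentage of listed nucleosomes (vertical axis) by positioning degree in percent (horizontal axis), 1 line per library, with a dotted line at 27.9%, the value of an even spread. MIC heavy 2 centres on 45.4% and the MAC libraries on 61.5 to 72.1%; MAC heavy 1 ends sharply near 60% because the list tracked it.

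The extremes among individual listed nucleosomes illustrate the contrast but do not test it, and their intervals take no account of the choice. Among 2625 with at least 100 midpoints in MIC heavy 2 and 50 in every MAC library, the 3 largest losses and 3 largest gains against the MAC mean were picked after their values were seen. At scf_8254811, positions 308038 to 308184, the degree was 30.9% in MIC heavy 2 (95% interval 23.6 to 39.0%) and 86.3% in MAC heavy 2 (81.2 to 90.5%). At scf_8254617, positions 854176 to 854322, it was 35.3% in MIC heavy 2 and 94.9% in MAC heavy 2. The nucleosome at scf_8254406, positions 730084 to 730230, had 31.2% in MIC heavy 2 and a MAC mean of 81.1%. At the 3 gains MIC heavy 2 lay between the MAC heavy libraries, and the MAC mean was lowered by MAC light. At scf_8254436, positions 46183 to 46329, the degree was 83.9% in MIC heavy 2, 68.7% and 87.8% in MAC heavy and 39.0% and 48.3% in MAC light. At scf_8254216, positions 32030 to 32176, it was 66.9% in MIC heavy 2, 67.9% and 47.5% in MAC heavy and 38.5% and 35.2% in MAC light. At scf_8255528, positions 1134 to 1280, it was 54.5% in MIC heavy 2, 62.1% and 47.0% in MAC heavy and 44.0% and 23.2% in MAC light, and the gain was absent against the mean of MAC heavy alone (-0.005 points). No annotation of these scaffolds was used here, so the genes at these positions are not named.

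The comparison of MAC light with MAC heavy asks how these measures differed with the level of digestion within 1 nucleus. Fragment density along the scaffolds was much more uneven in MAC heavy. The CV of fragments per 1 kb window was 91.0% and 92.2% in MAC heavy and 23.2% and 23.7% in MAC light, where counting noise alone gave about 8% after thinning. Windows holding over 2 times the median made up 22.4% of windows in each MAC heavy library and 0.00322% in each MAC light library. Across 93137 windows, which are not independent replicates, density correlated within MAC heavy (Spearman rho 0.907) and within MAC light (0.861), and between them at 0.263 to 0.416. The difference in CV, -68.2 points, far exceeded the spread between replicates (exact permutation test, p = 0.333, the smallest possible).

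**Figure D5:**
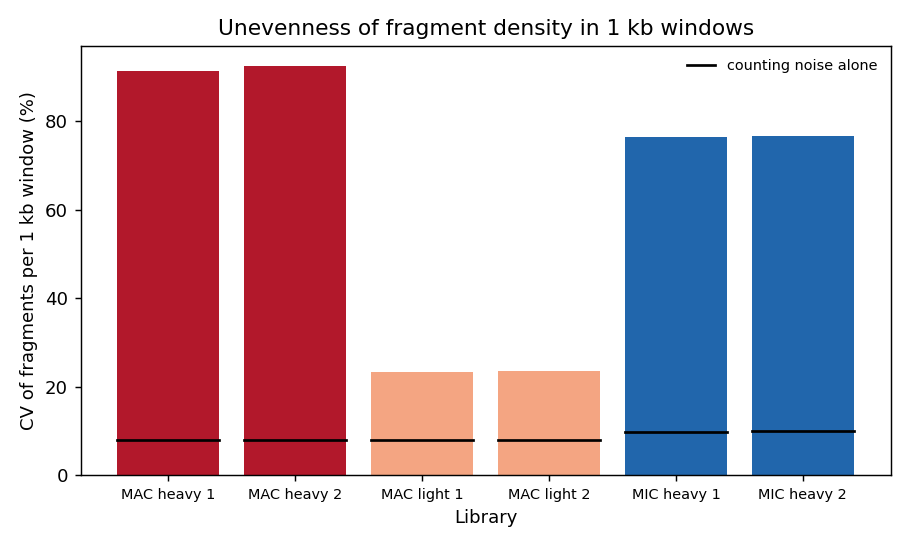
CV in percent of fragment counts per 1 kb window (vertical axis) for each library (horizontal axis), thinned to 1 size; black lines mark the CV from counting noise alone. Both MAC light libraries stay under 24% and the other 4 libraries above 75%.

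Of 102085 windows of 1 kb tested, 25920 were higher and 31198 lower in MAC light than in MAC heavy (edgeR), and 24270 and 21769 of these differed by more than 2-fold. Among the named windows the largest losses in MAC light lay on 2 very short scaffolds. The only window of scf_8253895 held 579 and 573 CPM (counts scaled to a common library size) in MAC heavy and 18.1 and 18.0 in MAC light (log2 fold change -5.00 ± 0.0950 SE, adjusted p = 0.000928 by edgeR), and window 1 to 1000 of scf_8254915 held 975 and 808 against 35.5 and 30.0 (-4.77 ± 0.158 SE). On a long scaffold, scf_8254650, the 3 adjacent windows from 315001 to 318000 had log2 fold changes of -3.97, -3.88 and -4.25. In the other direction, scf_8254459 from 193001 to 194000 rose by 2.23 ± 0.305 (SE), from 2.37 and 3.90 CPM in MAC heavy to 14.7 and 14.4 in MAC light. The window at scf_8254803 from 1216001 to 1217000 rose by 2.17. All 16 windows named by the rule lay between -5.00 and -3.81 or between 1.75 and 2.23. The smallest gain, 1.75 at scf_8254576 from 28001 to 29000 (adjusted p = 0.0466 by edgeR), was 1.09 without MAC heavy 1 and 2.96 without MAC heavy 2. It lost its call with DESeq2 size factors, in DESeq2 and in 140 to 160 bp fragments (adjusted p of 0.0512, 0.0665 and 0.0854), as did scf_8254798 from 89001 to 90000 in the latter (0.0511). The rule required a mean above the median and so left out windows sparse in MAC heavy. Over the 10210 windows lowest in MAC heavy the median log2 fold change was 3.45, and over the 10209 highest it was -1.81. Both classes were defined on MAC heavy itself, so part of each value is built in. Scaled by total fragments alone, 35830 windows were higher and 20272 lower and the median moved from -0.05 to 0.39, so the balance of directions depended on scaling. The number past the threshold was 86901 without MAC heavy 1, 89017 without MAC heavy 2, 34741 without MAC light 1 and 34046 without MAC light 2.

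Nucleosomes were placed slightly less sharply in MAC light at the deposited calls. Over called nucleosomes with at least 20 midpoints, 193576 to 210331 per library, the median degree was 50.0% and 48.6% in MAC heavy. It was 45.8% and 44.4% in MAC light, a mean difference of -4.14 points without overlap (exact permutation test, p = 0.333). Around the deposited calls the neighbours in MAC light lay at 200, 400 and 600 bp, but at 210, 410 and 610 bp around its own calls. How the deposited calls were chosen is not given. If they followed MAC heavy, part of this difference is built in. More nucleosomes could be called per Mb in the even MAC light libraries, 4139 and 4170, than in MAC heavy, 2355 and 2452. At 18.9 fragments per kb in place of 152, with all lengths kept, this reversed, to 70.9 and 74.8 in MAC light and 565 and 551 in MAC heavy, so the order depended on depth. The degree at new calls in MAC light minus MAC heavy was -4.27 points, but it turned to 3.39 points at 18.9 fragments per kb, with overlapping libraries, and to 14.4 points in 140 to 160 bp fragments at that depth, without overlap. The repeat length of MAC light exceeded that of MAC heavy by 3.0 bp and its array amplitude was lower by a mean of 19.8 points, both without overlap between libraries. The difference in amplitude was -10.2 points without MAC heavy 1 and -29.4 points without MAC heavy 2. Of 178482 nucleosomes tested singly, 0 passed the threshold in edgeR and 11241 (6.30%) had an unadjusted p under 0.05, with a median log2 ratio of -0.16. Without MAC heavy 1 the number passing was 3299 and without MAC heavy 2 it was 16. In simulated data of the same depth, with an assumed spread between libraries, 6.06% of 4-fold losses were recovered when 200 nucleosomes changed. When many changed, 94.9% of 4-fold and 16.5% of 1.5-fold losses were recovered. Recovery depends on that spread, so these shares need not hold for the real test.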

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

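The split by neighbours, both weightings and the test against MAC fragments in the MIC preparation were chosen after the result was seen. Listed nucleosomes were split by the deposited calls around them, into 17005 inside arrays, with called neighbours at 170 to 230 bp on both sides, and 4938 isolated ones, with none within 300 bp. Every MAC library was less sharply placed at isolated nucleosomes, whereas MIC heavy 2 was more sharply placed there. The classes rest on calls on MAC scaffolds and the list tracked MAC heavy 1, so the MAC direction may be built into the split in part. The mean degree at isolated minus array nucleosomes was -2.92 and -4.98 points in MAC heavy 1 and 2, -10.6 and -10.2 points in MAC light 1 and 2, and 3.87 points (95% bootstrap interval 3.52 to 4.21, over nucleosomes) in MIC heavy 2. The MIC medians were 43.8% inside arrays and 47.7% at isolated nucleosomes. Listed nucleosomes outside these classes lay between, at 46.4% for the 22703 with 1 neighbour at 170 to 230 bp and 44.3% for the remaining 3208. Those 3208 were thus nearly as low as the arrays in MIC heavy 2, and they had the lowest median in every MAC library. The opposite direction in MIC heavy 2 drew attention, and the difference between the nuclei was not tested, since 1 MIC library was measured here.

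Weighted alike over the MIC fragment count, the difference was 3.49 points (3.11 to 3.87), which argues against unequal depth as the whole explanation. The classes also differed in MAC degree, but this was lower at isolated nucleosomes and MIC degree rose with MAC degree, so weighting both classes alike over 5-point bins of the mean MAC degree was bound to raise the difference; it gave 6.74 points (6.39 to 7.08) and decides nothing. MAC fragments in the MIC preparation were not tested apart from the 3.87 points that define the pattern. A difference between the nuclei stays open, untested.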

How the results depend on the processing

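Of 184 alternative values of 24 results, 163 held: differences of library means by keeping their direction, since 2 libraries against 2 cannot pass a threshold; counts of calls by staying within 1.5 times the reported count; the degree at listed nucleosomes within 1 SD of MAC heavy; list sharing by an equal percentage. The list-sharing values are counted among the 163 but could not have failed, because that share was fixed in advance. In 140 to 160 bp fragments MIC and MAC heavy kept their direction but overlapped in repeat length and in CV. With fragments of 140 to 160 bp, the windows past the threshold for MAC light versus MAC heavy numbered 37422 against 57118; the cause was not tested. For new calls, that alternative also lowered the depth from 152 to 18.9 fragments per kb, so all lengths were thinned to 18.9 as well, an alternative chosen after seeing the data. In 140 to 160 bp fragments and at that depth with all lengths, calls per Mb turned from 343 to -217 and -250 for MIC minus MAC heavy, from 1751 to -513 and -485 for MAC light minus MAC heavy, and from -1409 to 296 and 235 for MIC minus MAC light, so lower depth alone turned them. The degree of calls in MAC light minus MAC heavy turned from -4.27 to 14.4 and 3.39 points, on 619 to 878 measured calls per MAC light library; the cause was not tested. Leaving out 1 library gave 34046 to 89017 windows, 0 to 3299 nucleosomes for positioning in MAC light versus MAC heavy, 22815 to 30952 for MIC versus MAC heavy, and -18.5 to 16.5 bp for the length of MIC minus MAC heavy fragments, and -35.0 to 0 bp for MIC minus MAC light. A fit that left 1 library in a group assumed that it varied like the others. With MAC light in place of MAC heavy, an alternative chosen after seeing the data, 11756 nucleosomes passed and the median degree of MIC heavy 2 lay -17.7 points from MAC, against -25.6 points. MAC light and MAC heavy libraries of the same replicate number did not deviate together (correlation 0.0164 over windows and -0.0164 for positioning); with a replicate block, 60346 windows and 1 nucleosome passed. No paired analysis was possible because MIC heavy 2 is the only MIC library with counts at called nucleosomes, in the test of single nucleosomes. Within replicate numbers, taken after seeing the data, MIC minus MAC heavy was 2.0 and -4.0 bp in length and -24.1 and -9.14 points in the CV of 140 to 160 bp fragments, whose repeat length differed by -5.10 and 0.2 bp; array amplitude, the degree of calls and the CV were lower in the MIC within both numbers in every alternative run. Against MAC heavy alone, the gain at scf_8255528 became -0.005 points. Of 176 alternative values of the 16 named windows, 172 kept their call, 4 lost it and 0 turned. Not run were tests needing genes, GC content or all 6 libraries on shared coordinates, the MIC counts with other windows, lengths or without repeats, positioning of MAC light in 140 to 160 bp fragments, where 0 nucleosomes had 20 midpoints in every library, and the MIC repeat length after smoothing over 61 bp, where 1 library showed 1 peak. MAC light had a median of 44 and 34 midpoints at listed nucleosomes, but whether depth limited its calls was not settled: with at least 50 midpoints in every library, 0 of 7489 nucleosomes passed in edgeR and 580 had an unadjusted p under 0.05.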

Other observations

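The tests in this part were chosen after the results were seen, except the array amplitude in 140 to 160 bp fragments. The deposited calls were themselves spaced like the arrays: the commonest distance above 160 bp between successive centres was 197 bp, while 27097 of 251305 distances (10.8%) were exactly 148 bp, the smallest in the list. Of the 46816 called nucleosomes with neighbours at 170 to 230 bp on both sides, 47.6% were on the shorter list, against 19.4% of the 35055 without a neighbour within 300 bp. Across the 47854 measured nucleosomes, which are not replicates, the degree in MIC heavy 2 correlated with MAC heavy 2 at Spearman rho 0.305 and with MAC heavy 1 at 0.119, after thinning to 20 midpoints, and with MAC light at 0.0832 and 0.0613. The MAC heavy pair correlated at 0.249 on the same measure; the list truncates MAC heavy 1 near 60%, and MIC heavy 2 and MAC heavy 2 share a replicate number and short fragments. Occupancy in MIC heavy 2 followed the same order, with rho 0.533 for MAC heavy 2, 0.363 for MAC heavy 1, and -0.0658 and -0.104 for MAC light 1 and 2. With the MAC libraries, but not MIC heavy 2, restricted to fragments of 140 to 160 bp, at 15491 nucleosomes, the degree in MAC heavy 2 correlated with MIC heavy 2 at 0.228 and that in MAC heavy 1 at 0.105, against 0.244 and 0.0944 with all lengths at the same nucleosomes.

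The faint arrays and blunt positions of the MIC were weighed against technical explanations. The values argue against unequal fragment length as the whole cause, since among 140 to 160 bp fragments the highest MIC amplitude was 29.2% and the lowest MAC amplitude 45.1%. They argue against small unplaced supercontigs too, since on scaffolds of at least 500 kb the highest MIC amplitude was 9.74% against 50.5%. A list chosen on a MAC library would favour the MAC, yet at nucleosomes called in each library itself the highest MIC degree was 37.1% and the lowest MAC degree 43.3%. This argues against the list as the whole cause only. At own calls, on other loci, MIC heavy averaged 36.9% and MAC heavy 47.8%. On the list the medians lay further apart, at 45.4% in MIC heavy 2 and 70.0% and 72.1% in MAC heavy, so part of that difference may come from the list. How far the MIC was digested and isolated, repeated DNA inside large supercontigs, and a biological difference between the nuclei remain open, the last as a hypothesis.

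The uneven density of MAC heavy was weighed in the same way. With identical fragments counted once the lowest MAC heavy CV was 89.2% against 23.5% for the highest MAC light CV, and in 140 to 160 bp fragments 85.7% against 31.6%, which argues against repeated fragments and fragment length as the whole cause. The gel-purified MAC light 2 had a CV of 23.7%, close to 23.2% in MAC light 1 from the gradient, but as it was the only gel-purified MAC light library, an effect of the gel stays open. Greater loss of accessible or AT-rich DNA under heavy digestion may be the cause, which would need the genome sequence to test.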
